A study of Mus musculus with 16 samples.

How the data were processed

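LT-HSCs were sorted from the bone marrow of mice of 4 genotypes given saline or pegylated IFNα (25 µg/kg in 100 µl, under the skin, 24 h), and 10x Genomics 3' libraries were made, 1 cDNA and 1 hashtag library per genotype and treatment, 16 samples in all. The labels name the chemistry as V3 in one field and as v2 in another. The deposited values are raw UMI counts per gene and cell and raw hashtag counts per cell, made by the authors with STARsolo 2.7.9a and R 4.2.0 on build mm10, per the submitters' processing notes. The gene annotation release, the authors' cell filter and their clustering tool are not given in the sources used here. The authors also deposited for each cell its genotype, treatment, cluster and biological replicate. Counts covered 55491 features, of which 55141 had a symbol in the GENCODE reference held here, 346 had none, and 4 were added transgene features (CreERT2 and segments of human JAK2). Genes without a symbol were kept in library totals. Counts were not normalized before deposit.

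All 41187 deposited cells were used, each with at least 2000 UMIs and 913 genes and at most 18.3% mitochondrial counts, and no further cell filter was applied. In every cell the hashtag with the highest count matched the deposited replicate. Doublets were treated as the authors left them: a test for cells whose top hashtag held fewer than 10 counts or less than 3 or 5 times the second removed 0 cells, the lowest ratio being 9.12, and doublets within a replicate were not searched for. In Dnmt3a-/- libraries the third hashtag had a highest count of 1, so these hold 2 replicates. Total UMIs were 13933462 and 36942358 in wild type given vehicle and IFNα, 20652815 and 46119811 in Dnmt3a-/-, 101044061 and 103002297 in JAK2-V617F, and 92207672 and 98242529 in the double mutant. Median UMIs per cell were 13490.5 and 27653, 11529.5 and 16880.5, 9224 and 8524, and 8830 and 12904.5 in the same order. In the smallest library a count of 3 stands for 0.215 CPM, which was used as the floor for features with 0 counts.

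Counts were summed over the cells of each library, and genes with at least 5 CPM in at least 2 libraries were tested, 10864 in all. edgeR 4.0.16 (TMM normalization, quasi-likelihood F test, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05) was run in R 4.3.3. Effects of IFNα, JAK2-V617F, Dnmt3a loss, Dnmt3a loss within JAK2-V617F and the interaction of both mutations came from an additive fit of genotype and treatment with 3 residual degrees of freedom (common biological coefficient of variation 0.162). The interactions of IFNα with each mutation came from a fit with 1 residual degree of freedom (0.106). Both share 1 estimate of the spread over all 8 libraries. The labels did not tell what the hashtags mark, so sums per library and replicate (22, with 14 residual degrees of freedom, 0.0701) were planned as an alternative and are given beside the library values. The fits over replicate sums within 1 genotype or 1 treatment were added after the data were seen. Replicates of a group shared a library, so these fits do not see the spread between libraries.

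Gene lists, 28 in all, were fixed before the data were examined. They were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, with camera using an estimated correlation, and with fry, adjusted by Benjamini-Hochberg over the lists of a comparison. Counts of members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are named so. Within a genotype at the library level there is 1 library per group, so ratios with a pseudocount of 1 CPM are given with no test, and the median of a list is placed among 10000 random lists of the same size matched on mean expression. The share of cycling cells is the share with at least 3 UMIs over the G2 and M list after thinning each cell to 5000 UMIs, compared over libraries by exact sign-flip or permutation tests. Thinning left out 18 and 11 wild type cells given vehicle and IFNα, 30 and 39 of Dnmt3a-/-, 470 and 872 of JAK2-V617F and 535 and 161 of the double mutant, which had fewer UMIs.

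Named genes follow rules set at the same time: for each effect the 10 genes with the largest rise and the 10 with the largest fall among those that passed, with a mean of at least 20 CPM, the same direction in each matched pair of libraries and a gene symbol that is not a clone name, or the 5 with the smallest p where fewer than 3 passed. From a list up to 4 members that passed with the largest change could be named, or the 2 most abundant if none passed, and for interactions the 5 genes with the smallest p under the same limits. Jak2, the transgenes, Dnmt3a and the genes of the sort gate were named in any case. A part of the genes so chosen is printed. Gene positions are from GENCODE vM21 on GRCm38, matched by gene ID. Counting by strand is not stated in the labels, and reads shared by near copies could be assigned to either.

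Each comparison was tested on simulated data with planted changes, drawn with a biological coefficient of variation of 0.15 for libraries and 0.07 for replicate sums. The value for libraries is near that of the additive fit but above that of the interactions with IFNα. Their recovery thus holds for a wider spread than fitted. At a planted change of 2-fold edgeR over libraries recovered 98.5% of genes for IFNα, 98.4% for JAK2-V617F, 100% for Dnmt3a loss, 86.6% for Dnmt3a loss within JAK2-V617F, 30.2% for the interaction of both mutations, 32% for that of IFNα with JAK2-V617F and 37.7% for that of IFNα with Dnmt3a loss, and at 4-fold 100% in each. At 1.5-fold it recovered 50%, 49.2%, 55.4%, 15.9%, 6.9%, 6.9% and 4% in that order. False calls made up between 1.48% and 7.22% of calls. Over replicate sums at least 95.5% were recovered at 2-fold, with 3.4% to 8.02% false calls. A planted shift of 1 list was found by camera in all 7 comparisons, with at most 1 of 27 other lists called. Simulated samples are independent, so they say nothing of cell composition that differs between libraries or of false calls where replicates share one, as here.

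Alternatives planned were DESeq2 1.42.0 in place of edgeR, no low count filter and a stricter one (20 CPM), equal depth (830 cells and 8272286 UMIs per library), only the 5325 cells of the largest cluster (cluster 6), no cycling cells, sums per replicate with and without the replicate number as a block, each library left out, the other list tests, other pseudocounts, other UMI limits for cycling cells, and hashtag singlets. Alternatives added after the data were seen leave out the Dnmt3a-/- pair of libraries, whose vehicle replicates carried Xist and whose IFNα replicates carried Y transcripts, replicates 3 of the double mutant in both treatments, which differ from its other replicates in Xist and Y counts and, under IFNα, in transgene counts, or the cells of clusters 11 and 17, which are led by erythroid genes. The last leaves out 38 and 549 wild type cells given vehicle and IFNα, 1 and 839 of Dnmt3a-/-, 3 and 677 of JAK2-V617F, and 5 and 722 of the double mutant. The largest cluster holds 27 to 1547 cells per library. Shares of cells per cluster were not analysed here, because clusters of treated and untreated cells are defined by genes that the treatment changes. The t-SNE coordinates were not used here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.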

Results

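The series holds single-cell RNA counts of long-term haematopoietic stem cells (LT-HSCs), sorted from mouse bone marrow as Lin- Kit+ Sca-1+ CD150+ CD48- cells. Mice of 4 genotypes were compared: wild type, Dnmt3a-/-, JAK2-V617F, and the double mutant JAK2-V617F;Dnmt3a-/-. Animals aged 8 to 10 weeks had received vehicle or 25 µg/kg pegylated IFNα under the skin, and cells were taken 24 h later. The question was whether loss of Dnmt3a, a DNA methyltransferase often mutated in clonal blood disease, alters how JAK2-V617F stem cells respond to interferon. There was 1 cDNA library per genotype and treatment, 8 in all, with 41187 cells and 512145005 UMIs. Hashtags in each library gave 22 biological replicates, 2 per library in Dnmt3a-/- and 3 in the others. Library size was uneven: wild type had 830 vehicle and 996 IFNα cells, Dnmt3a-/- 1620 and 2068, JAK2-V617F 9767 and 10154, and the double mutant 9330 and 6422. Median UMIs per cell ran from 8524 in JAK2-V617F under IFNα to 27653 in wild type under IFNα. Nothing in the labels says that replicates came from separate animals, and replicates of a group shared a library, so the p-values measure the spread of these samples. Sex was not the same throughout: both Dnmt3a-/- vehicle replicates and replicate 3 of the double mutant given vehicle carried Xist (2114, 2101 and 1860 CPM) and few or no counts of the Y gene Ddx3y (0, 0 and 0.31 CPM), replicate 3 of the double mutant under IFNα carried neither (0.229 and 0.275 CPM), and the other replicates carried Ddx3y. Values after ± are standard errors of log2 fold changes.

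Dnmt3a itself (chromosome 12, 3806007 to 3914443, GRCm38) was lower in the Dnmt3a-/- libraries and still counted. It stood at 58.7 and 32.2 CPM (counts over the library's total, scaled alike in each library) in wild type given vehicle and IFNα, 36.5 and 17 in Dnmt3a-/-, 63.6 and 58.7 in JAK2-V617F, and 35.3 and 24.1 in the double mutant. The log2 difference with Dnmt3a loss was -0.98 ± 0.14 over 8 library sums (edgeR adjusted p = 0.255) and -0.96 ± 0.04 over 22 replicate sums (edgeR adjusted p = 8.3e-13). A 3' tag that lies outside the deleted part of a gene checks nothing about the deletion, so these counts neither prove nor exclude it. The human JAK2 transgene, counted over exons 3 to 12, had 0 counts in all 4 libraries of wild type and Dnmt3a-/- mice. It reached 59.9 and 59.1 CPM in JAK2-V617F given vehicle and IFNα, and 28.5 and 33.1 CPM in the double mutant. By replicate it was 28.6, 30.7 and 26 CPM in the double mutant given vehicle and 20.1, 24.4 and 48 under IFNα, so replicate 3 alone put the IFNα library above the vehicle library. Against a floor of 3 counts in the shallowest library without it, 0.215 CPM, that is at least 132-fold more in the lowest of the 4 libraries. CreERT2 was counted in every genotype, with 114 CPM in wild type and 68.5 CPM in JAK2-V617F given vehicle. It differed between replicates of several groups, with 75.5 and 175 CPM in Dnmt3a-/- given vehicle, 88.2, 88.4 and 123 in the double mutant given vehicle and 125, 146 and 67.2 under IFNα, and so marks no single replicate. Dnmt3a of replicate 3 of the double mutant under IFNα (25.5 CPM) was near the others (21.5 and 26.8).

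**Figure D1:**
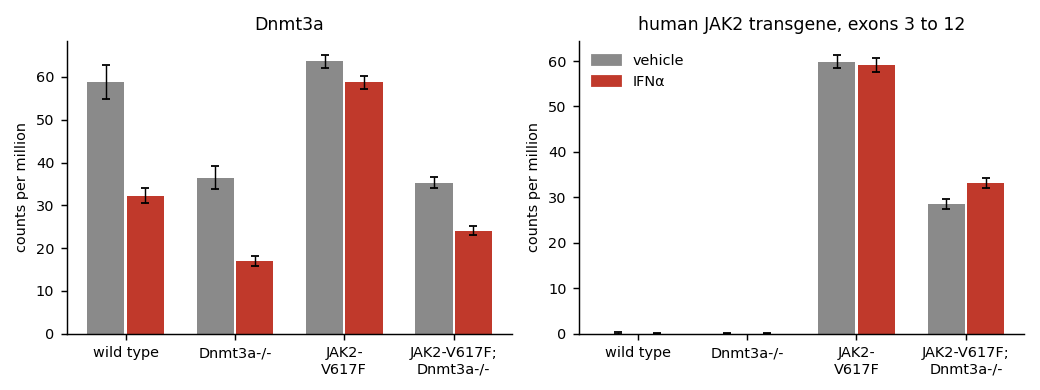
CPM of Dnmt3a and of the human JAK2 transgene (exons 3 to 12) in the 8 libraries; bars are library values and error bars 95% Poisson intervals of the counts. Dnmt3a falls from 58.7 in wild type to 36.5 in Dnmt3a-/- given vehicle, and the transgene is seen only in the 4 JAK2-V617F libraries.

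IFNα switched on the antiviral programme of LT-HSCs in all 4 genotypes. Of 54 tested interferon-stimulated genes, 50 rose, 0 fell and 4 did not pass, with a median log2 fold change of 1.57. Irf7, the transcription factor that amplifies type I interferon signalling (chromosome 7, 141262706 to 141266481), had the smallest adjusted p (4.24 ± 0.10, adjusted p = 1.5e-04) and in CPM went from 12.8 to 190 in wild type, 16.9 to 284 in Dnmt3a-/-, 14.6 to 291 in JAK2-V617F and 18.2 to 400 in the double mutant. Ifit3 (4.17 ± 0.41), which binds viral RNA complexes, Ifi27l2a (4.06 ± 0.17), and Usp18 (3.06 ± 0.16), which damps the interferon receptor, rose too. Genes that load peptides on MHC class I rose as well, 14 of 17 with a median of 0.42, among them the peptide transporter Tap1 (0.96 ± 0.06) and H2-T22 (0.89 ± 0.07). Counts of Ifit3, Ifi27l2a and H2-T22 are uncertain, since reads could be shared with close copies such as Ifit3b, Ifi27l2b and other H2-T genes. Across all genes edgeR called 3192 of 10864, 1357 up and 1835 down, at an adjusted p under 0.05, and 3191 of these were also called over replicate sums. Camera with its preset correlation called the interferon-stimulated list (adjusted p = 6.6e-27) and the MHC class I list (adjusted p = 2.1e-07); the values were 0.579 for each with an estimated correlation. Adjusted over the list alone, 51 interferon-stimulated genes passed. The number of called genes rested much on the Dnmt3a-/- pair: without it edgeR called 108, and with single libraries left out 90 (Dnmt3a-/- IFNα), 107 (Dnmt3a-/- vehicle), 376 (double mutant IFNα), 917 (double mutant vehicle), 1290 (wild type vehicle) and 1292 (wild type IFNα). Ifit3 lost its call without the vehicle or the IFNα library of Dnmt3a-/- mice (4.25 and 4.24).

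Genes that mark stem cell identity moved the other way. Of 25 such genes, 14 fell, 1 rose and 10 did not pass, with a median of -0.93. Hlf, a transcription factor that keeps HSCs quiescent (chromosome 11, 90336536 to 90390895), went in CPM from 478 to 60 in wild type, 613 to 115 in Dnmt3a-/-, 458 to 241 in JAK2-V617F and 438 to 198 in the double mutant (-1.82 ± 0.35, adjusted p = 0.0232). Fgd5 (-1.79 ± 0.40), Procr (-1.73 ± 0.36) and Mecom (-1.70 ± 0.34) fell too, and so did the cell cycle inhibitor Cdkn1c (-2.003 ± 0.26). Megakaryocyte genes rose: 13 of 17 passed and none fell, with a median of 1.63, led by the platelet chemokine Pf4 (3.67 ± 0.48), and with the platelet receptor part Gp1bb (2.35 ± 0.30) and Treml1 (2.14 ± 0.27). Markers of other cells moved with these groups. Erythroid genes were up, 11 of 17 with 1 down and a median of 1.56, including Klf1 (3.27 ± 0.48) and Car1 (6.21 ± 1.60).

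Mast cell genes rose in 3 of 3 (median 2.13, Ms4a2 (3.65 ± 0.28)), and Ccl5 (4.25 ± 0.17) and Nkg7 (1.59 ± 0.18) rose as well, the only 2 of 10 T and NK cell genes with enough counts to test; Cd3e, Cd4 and Cd8a were among the 8 too low, so the pair does not show such cells. Lymphoid priming genes fell in 3 of 4 (median -1.25, Flt3 (-1.75 ± 0.25)). Camera with preset correlation called HSC identity (adjusted p = 2.6e-04), megakaryocyte (6.4e-07), erythroid (4.3e-04), mast cell (0.0128), T and NK (0.00563) and lymphoid genes (0.0106). With an estimated correlation the adjusted p was 0.579 to 0.714. No list call at the library level in any comparison held with an estimated correlation. That test rests on 3 or 1 residual degrees of freedom and did not call even the interferon-stimulated list for IFNα (0.579). A call lost in it therefore decides little. Without the cells of the clusters 11 and 17, which are led by erythroid genes and came almost only from IFNα libraries, the HSC identity median shrank to -0.41 (14 down, 2 up) and the megakaryocyte median was 1.76. The mast cell median was 1.64 and that of erythroid genes 0.38 in that fit, and camera no longer called mast cell genes. Clusters were drawn by expression, so a fit to part of them selects cells partly by the genes tested and does not tell a change within cells from a change of cells. In the cells of the largest cluster alone the medians were -0.24 for HSC identity (adjusted p = 0.00531 by camera), 0.11 for megakaryocyte, -0.12 for erythroid and -0.01 for lymphoid genes, and camera called none of the last 3. Ccl5 and Nkg7 kept a median of 3.05 there (adjusted p = 0.00233), while Procr turned to 0.02 and Flt3 to 0.42. Without the vehicle library of Dnmt3a-/- mice, Hlf (-1.64), Fgd5 (-1.51), Procr (-1.53), Mecom (-1.59), Cdkn1c (-1.84), Pf4 (3.45), Gp1bb (2.19), Treml1 (2.20), Car1 (5.08) and Flt3 (-1.60) lost their calls, with the same values without its IFNα library. Without the double mutant IFNα library Hlf (-2.05), Procr (-2.01) and Mecom (-1.91) lost them, Fgd5 without either double mutant (-2.05 and -2.04) or wild type library (-1.44 each), and Car1 without either double mutant (6.07 and 6.08) or JAK2-V617F library (5.98 each).

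**Figure D2:**
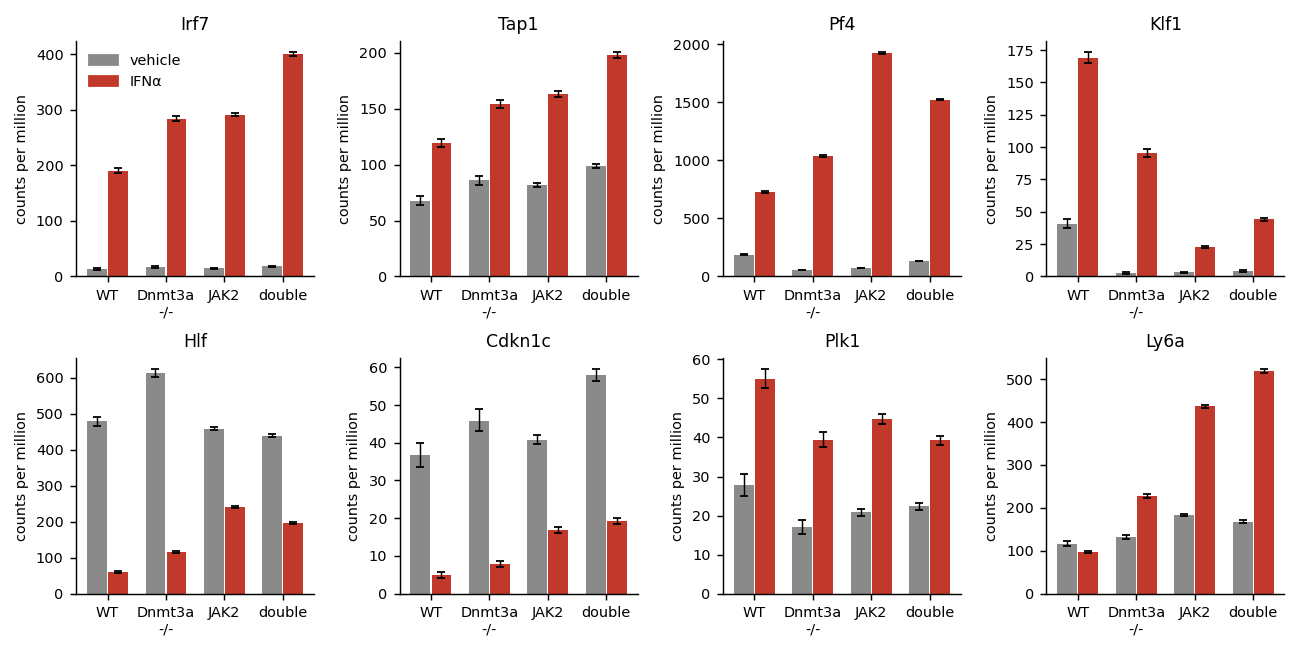
CPM of 8 genes in the 8 libraries (WT, wild type; JAK2, JAK2-V617F; double, JAK2-V617F;Dnmt3a-/-), with 95% Poisson intervals of the counts as error bars. Irf7, Tap1, Pf4, Klf1 and Plk1 are higher under IFNα in each genotype, while Hlf goes from 478 to 60 in wild type and from 458 to 241 in JAK2-V617F.

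Cell division genes rose with IFNα. 17 of 20 genes of G2 and M phase were higher (median 0.66), among them the mitotic kinase Plk1 (1.07 ± 0.11) and the centromere histone Cenpa (0.99 ± 0.09), as were 4 of 21 genes of S phase (median 0.27, Rrm2 (0.62 ± 0.15)). Chaperones (4 of 9, median 0.53, Hspa1b (1.63 ± 0.33), which could share reads with Hspa1a) and nuclear genes of oxidative phosphorylation (8 of 22, median 0.28, Atp5g1 (0.61 ± 0.17)) rose with them. Camera adjusted p was 5.6e-10 for G2 and M, 7.9e-04 for S phase, 0.0254 for chaperones and 4.3e-04 for oxidative phosphorylation; with an estimated correlation it was 0.579 for G2 and M and 0.714 for the other 3. Adjusted over the list alone, 18, 0, 4 and 9 genes passed. The share of cells with at least 3 UMIs of G2 and M genes, after thinning each cell to 5000 UMIs, was 21.7%, 19.5%, 22.5% and 24.6% in wild type, Dnmt3a-/-, JAK2-V617F and double mutant vehicle libraries. Under IFNα it was 49.9%, 38.5%, 40.1% and 40.3%. The mean was 42.2% (SD 5.21) against 22.05% (SD 2.09) in 4 pairs of libraries, a difference of 20.2 percentage points, with an exact sign-flip p = 0.13, the smallest that 4 pairs can give. In the largest cluster alone the medians were 0.12 for G2 and M, 0.05 for S phase and 0.17 for chaperones, none called by camera; without clusters 11 and 17 that of chaperones was 0.06, not called, and without either wild type library 0.40, not called. Rrm2, Hspa1b and Atp5g1 lost their calls without either Dnmt3a-/- (0.60, 1.58 and 0.49 each) or double mutant library (0.67 and 0.68, 1.31 and 1.32, 0.69 each), and Rrm2 and Atp5g1 without either wild type library (0.46 and 0.51).

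The share of cycling cells was 31.8% (SD 9.67) in the 4 JAK2-V617F libraries and 32.4% (SD 14.5) in the 4 others, a difference of -0.567 percentage points (exact permutation p = 1). It was 30.7% (SD 10.3) in the 4 libraries without Dnmt3a and 33.5% (SD 13.9) in the 4 with it, -2.83 percentage points apart (exact permutation p = 0.743). The SDs and tests mix vehicle and IFNα libraries, so they do not exclude an effect of genotype.

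**Figure D3:**
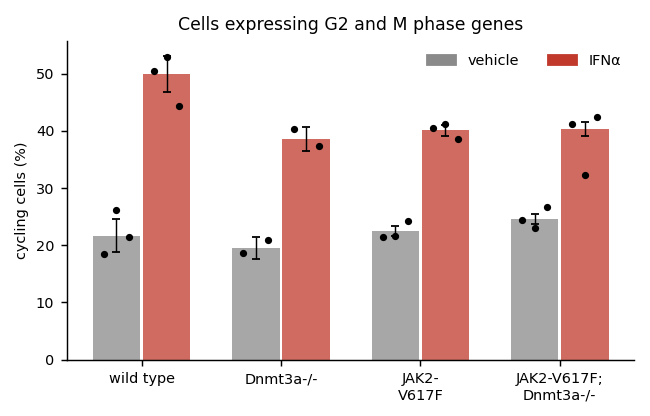
Percentage of cells with at least 3 UMIs of G2 and M phase genes after thinning to 5000 UMIs, by genotype and treatment; bars are libraries, error bars 95% binomial intervals and points biological replicates. Vehicle libraries lie between 19.5% and 24.6%, IFNα libraries between 38.5% and 49.9%.

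Within each genotype the interferon-stimulated genes rose in every background. The median log2 ratio of IFNα over vehicle library was 0.81 in wild type, 1.33 in Dnmt3a-/-, 1.47 in JAK2-V617F and 1.67 in the double mutant, above all of 10000 random lists matched on expression in each genotype. With 1 library per group these ratios carry no test. Over replicate sums edgeR called 44 genes of the list up and 3 down in wild type, 53 up in Dnmt3a-/-, and all 54 up in JAK2-V617F and in the double mutant. The medians were 1.08, 1.55, 1.55 and 1.62, and camera adjusted p was 3.9e-09, 2.1e-18, 1.1e-43 and 6.3e-41, against 0.575, 0.468, 0.0564 and 0.142 with an estimated correlation. Clusters 11 and 17 held 549 of the 996 wild type IFNα cells. Without them the medians were 1.29, 1.57, 1.53 and 1.58, wild type still lowest. In the largest cluster the library median of wild type was 1.65 with 27 IFNα cells. Over all cells HSC identity genes fell further without the transgene: 22 and 22 of 25 fell in wild type and Dnmt3a-/- (medians -1.46 and -1.26), against 13 and 17 in JAK2-V617F and the double mutant (medians -0.33 and -0.51). Without clusters 11 and 17 this contrast became smaller, with 17 and 15 down (medians -0.64 and -0.56) against 13 and 15 (medians -0.30 and -0.36). Over all cells Hlf changed by -2.85 ± 0.13, -2.26 ± 0.15, -0.94 ± 0.11 and -1.20 ± 0.11 in that order of genotypes. Camera adjusted p of HSC identity was 1.3e-07, 3.2e-06, 0.0164 and 1.7e-04, and with an estimated correlation 0.575, 0.468, 0.61 and 0.403. Over all genes 7907, 7184, 4684 and 5756 of 10864 were called by edgeR.

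**Figure D4:**
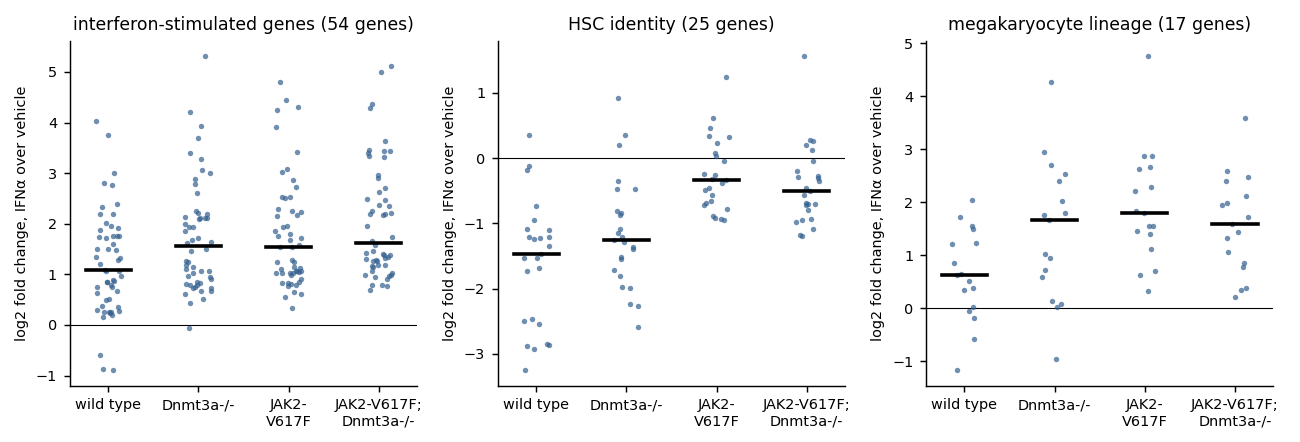
Log2 fold change of IFNα over vehicle for each gene of 3 lists in the 4 genotypes, fitted over replicate sums; each point is a gene and the black line the median. HSC identity medians run from -1.46 in wild type to -0.33 in JAK2-V617F, while interferon-stimulated medians lie between 1.08 and 1.62.

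The response to IFNα differed between libraries with and without the transgene in 1309 genes, 861 with a more positive and 448 with a more negative log2 change in the JAK2-V617F libraries. The fit left 1 residual degree of freedom, and the count was 122 without the cells of clusters 11 and 17, 107 without cycling cells, 28 in the largest cluster alone and 100 without replicates 3 of the double mutant, so it depends on which cells are counted. The genes with the smallest p were the RNA-binding Ybx3 (-1.91 ± 0.16, adjusted p = 0.00555), the phosphatase subunit Ppp2cb (-2.68 ± 0.25, adjusted p = 0.00774), the transporter Atp13a3 (-1.53 ± 0.17, adjusted p = 0.0115), the actin-binding Lsp1 (1.37 ± 0.16, adjusted p = 0.0115) and Cdk2ap1 (-1.30 ± 0.15, adjusted p = 0.0115). HSC identity genes lost less of their expression where the transgene was present, with 19 of 25 called more positive (23 adjusted over the list alone) and a median of 1.06. HSC ageing (8 of 16, median 0.95), lymphoid (3 of 4, 0.86), myeloid (4 of 7, 0.75), NF-κB target (5 of 13, 0.75), megakaryocyte (3 of 17, 0.66) and interferon-stimulated genes (12 of 54, 0.38) went the same way. Ribosomal proteins (11 of 83 called, -0.29), mitochondrial genome transcripts (6 of 16, -0.56), S phase (1 of 21, -0.40), oxidative phosphorylation (1 of 22, -0.39) and chaperones (3 of 9, -0.47) went down. Camera adjusted p was 3.9e-10 for HSC identity, 3.6e-09 for ribosomal proteins and between 2.3e-05 and 0.0286 for interferon-stimulated, ageing, mitochondrial, oxidative phosphorylation, S phase, NF-κB, megakaryocyte, lymphoid, chaperone and myeloid genes. With an estimated correlation it was 0.725 to 0.788. Without clusters 11 and 17 the medians were 0.34 for HSC identity and 0.36 for interferon-stimulated genes, both still called. Megakaryocyte genes turned to -0.05, now called lower (camera adjusted p = 0.0344, against 0.00962 for higher over all cells). Myeloid (0.19), lymphoid (0.15) and chaperone genes (-0.14) lost their calls, chaperones also without replicates 3 of the double mutant (-0.22). In the largest cluster alone the medians were -0.07 for HSC identity, -0.01 for interferon-stimulated, -0.16 for myeloid, -0.07 for lymphoid, 0.10 for chaperone, 0.17 for megakaryocyte, -0.11 for S phase and -0.02 for oxidative phosphorylation genes, none called by camera.

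Under IFNα, interferon-stimulated genes were higher in double mutant than in JAK2-V617F LT-HSCs, by an amount that rested in part on replicates 3 of the double mutant. In vehicle, the list had a median of 0.07, with 4 of 54 genes up over 3 against 3 replicate sums. Under IFNα, 33 rose and none fell, with a median of 0.39 (42 up and 1 down adjusted over the list alone). Ifit3 (1.07 ± 0.23), the nucleic acid sensor Zbp1 (0.91 ± 0.17), the ubiquitin-like Isg15 (0.73 ± 0.14) and Usp18 (0.57 ± 0.09) were higher in the double mutant under IFNα. In vehicle the same genes had Ifit3 0.32 ± 0.43, Zbp1 0.24 ± 0.20, Isg15 -0.04 ± 0.15 and Usp18 -0.11 ± 0.12. MHC class I genes followed, 4 of 17 up in vehicle (median 0.09) and 13 under IFNα (median 0.27). Camera adjusted p for interferon-stimulated genes was 0.383 in vehicle and 5.9e-09 under IFNα, with 0.703 under IFNα when the correlation was estimated. For MHC class I it was 0.0264 and 3.4e-07, and 0.972 and 0.402 with an estimated correlation. Over all genes edgeR called 1946 in vehicle and 3299 under IFNα; with 1 JAK2-V617F vehicle replicate left out the vehicle count was 1215, 1144 or 1236. The difference between the vehicle and IFNα values was tested only over both JAK2 backgrounds together. Replicates 3 of the double mutant, which stand apart by Xist and Y counts, under IFNα also by transgene counts, and over all genes (chi-squared per degree of freedom 20.1 and 29.4 against replicates 1 and 2 in vehicle and 20.5 and 10.7 under IFNα, while replicates 1 and 2 had 3.6 and 9.05 between them), carried much of that difference: without them the interferon-stimulated median was 0.13 in vehicle (13 up, camera adjusted p = 0.00111) and 0.20 under IFNα (28 up, 1 down, camera adjusted p = 3.4e-05), with 0.764 and 0.697 when the correlation was estimated. The response to IFNα then had a median of 1.42 in the double mutant against 1.54 in JAK2-V617F. MHC class I medians were 0.06 and 0.20, and edgeR called 3176 and 4374 genes.

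**Figure D5:**
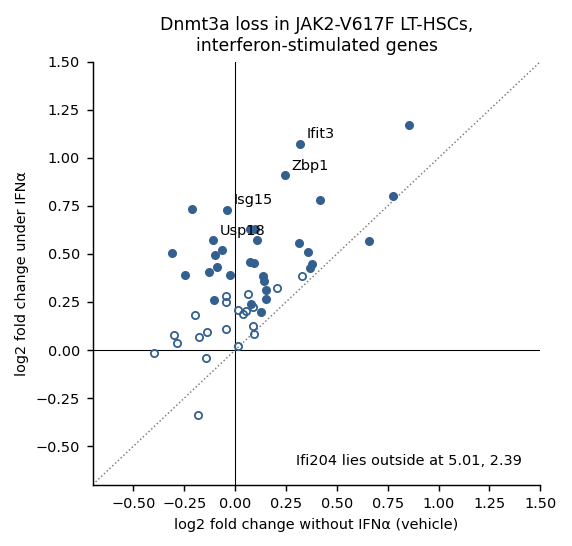
Log2 fold change of Dnmt3a loss in JAK2-V617F LT-HSCs for interferon-stimulated genes, without IFNα (horizontal) and under IFNα (vertical), fitted over replicate sums; filled points passed an edgeR adjusted p of 0.05 under IFNα and the dotted line marks equal change. Most points lie above the line, with medians of 0.07 and 0.39.

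Immediate early genes, which switch on within minutes of a stimulus, were lower in the double mutant library without IFNα and higher under it. With 1 library against 1 each time, genotype and library cannot be told apart. In vehicle, Fos (-2.73 ± 0.38) and Jun (-1.54 ± 0.24) were lower in the double mutant, and 5 of 12 genes of the list fell (median -0.28). Under IFNα 5 of 12 were higher (median 0.36), with Fos at 0.74 ± 0.43 and Jun at 0.09 ± 0.23, neither called, and the difference between the treatments was not tested in this background alone. By camera the adjusted p was 0.0264 in vehicle and 0.00251 under IFNα, and 0.972 and 0.703 with an estimated correlation. Ribosomal protein genes were slightly higher without Dnmt3a, 47 up and 3 down of 83 in vehicle (median 0.12, adjusted p = 7.2e-12, 0.972 with an estimated correlation).

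Across both JAK2 backgrounds, the response of the interferon-stimulated list to IFNα was larger without Dnmt3a, by a median log2 difference of 0.41 over library sums and 0.37 over replicate sums. No single interferon-stimulated gene passed over library sums (10 up and 1 down adjusted over the list alone), and 17 passed over replicate sums. Camera adjusted p was 7.9e-25 over libraries, 0.838 with an estimated correlation. Over all genes edgeR called 2 of 10864 over libraries, with 375 at an unadjusted p under 0.05, 14 by DESeq2 and 903 over replicate sums. The called pair was Xist (-11.01 ± 0.43, adjusted p = 1.3e-05) and Tsix (-4.49 ± 0.35, adjusted p = 0.00272), transcribed from opposite strands of the X inactivation centre, so that reads of one may count for the other. Xist was carried by the vehicle replicates named above and by no replicate under IFNα. Without replicates 3 of the double mutant Xist had -5.39 and Tsix -2.70, neither called, edgeR called 18 genes with Ermap (5.54) among them, and the interferon-stimulated median was 0.29 (camera adjusted p = 6.0e-10). Ermap (5.04 ± 0.69, adjusted p = 0.0851) came next. Immediate early (0.43), NF-κB target (0.25), erythroid (0.58), mast cell (1.15) and chaperone genes (0.26) were called more positive as lists and glycolysis genes (-0.16) more negative, with camera adjusted p of 2.2e-07, 1.5e-05, 1.6e-04, 1.6e-04, 0.00712 and 3.6e-04, and 0.838 for each with an estimated correlation. Adjusted over the list alone, 5 immediate early, 5 erythroid and 2 mast cell genes passed. The interferon-stimulated median was 0.50 without the cells of clusters 11 and 17, with 7 genes called up and 1 down (camera adjusted p = 3.4e-32), and 0.52 in the largest cluster alone, with 9 up and 1 down (camera adjusted p = 5.4e-13). Erythroid genes turned to -0.10 and -0.16 in these fits, and camera called neither these nor the chaperones (0.03 and 0.19), nor glycolysis genes in the largest cluster (-0.07). That cluster is led in part by interferon-induced genes such as Ifit3 and holds 27 wild type IFNα cells.

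JAK2-V617F raised Socs2 in LT-HSCs of both treatments, while targets of cytokine signalling as a group went both ways. Socs2, a STAT5 target that feeds back on JAK2 (chromosome 10, 95385362 to 95417180), went from 15.1 CPM in wild type to 157 in JAK2-V617F given vehicle, and from 6.25 to 84 under IFNα (3.07 ± 0.18, adjusted p = 0.0176). Besides the transgene segments, edgeR called Ifitm1 (1.49 ± 0.13, adjusted p = 0.044), an interferon-inducible membrane protein, Slc17a8 (3.64 ± 0.25, adjusted p = 0.0207), Gimap4 (2.85 ± 0.26, adjusted p = 0.0492) and Tnfsf13os (1.15 ± 0.10, adjusted p = 0.0492) up and Trib2 (-2.19 ± 0.18, adjusted p = 0.044) down, 8 of 10864 features with the transgene included. Slc17a8, Gimap4 and Trib2 are named here because they complete the called set, after their values were seen. Tnfsf13os is antisense to its neighbour, so reads of the neighbour may count for it. The cytokine receptor subunit Csf2rb (1.36 ± 0.13, adjusted p = 0.0537) and Id1 (2.76 ± 0.29, adjusted p = 0.0802) missed the threshold over libraries. Among STAT5 and STAT3 targets 1 of 15 rose (7 up and 2 down adjusted over the list alone), with a median of 0.37, which was 0.06 without the cells of clusters 11 and 17 (camera adjusted p = 0.417) and -0.01 in the largest cluster (0.855). Over replicate sums edgeR called 7104 genes and DESeq2 1145 over libraries. With single libraries left out the count was 2 (Dnmt3a-/- IFNα), 3 (wild type vehicle or JAK2-V617F vehicle), 4 (wild type, JAK2-V617F or double mutant IFNα), 6 (Dnmt3a-/- vehicle) or 7 (double mutant vehicle). Every called gene of the mouse genome had lost its call in at least 1 of these fits; Socs2 had 3.13, 3.00, 3.23 and 2.93 without the wild type vehicle, wild type IFNα, Dnmt3a-/- vehicle and Dnmt3a-/- IFNα libraries, and Ifitm1 1.55, 1.43, 1.59 and 1.40.

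As lists, HSC identity (0.60), myeloid (0.61), STAT target (0.37), NF-κB target (0.28) and interferon-stimulated genes (0.21) were higher with the transgene. Erythroid (-1.12), mast cell (-2.01), chaperone (-0.36), oxidative phosphorylation (-0.15) and ribosomal protein genes (-0.14) were lower. These medians average vehicle and IFNα libraries and so show no difference in untreated cells alone. Several of these lists, HSC identity among them, were also called above for their response to IFNα. Ifitm1 was the 1 HSC identity gene that passed, and no erythroid gene passed among all genes, while 3 and 12 did when adjusted over their list alone. Camera adjusted p was 2.2e-06 for ribosomal proteins, 2.9e-05 for HSC identity and for erythroid genes, 0.0039 for oxidative phosphorylation, 0.00815 for interferon-stimulated, 0.0176 for mast cell, 0.0262 for chaperone, 0.0313 for STAT and NF-κB targets and 0.0337 for myeloid genes. With an estimated correlation it was 0.809 for all 10. Without the cells of clusters 11 and 17 only 2 lists were called, ribosomal proteins among them; the HSC identity median was 0.14, that of erythroid genes -0.20, and oxidative phosphorylation turned to 0.06, while interferon-stimulated (0.19), myeloid (0.14), NF-κB (0.02), mast cell (-1.62) and chaperone genes (-0.12) lost their calls. In the largest cluster alone HSC identity turned to -0.14 and oxidative phosphorylation to 0.09, and interferon-stimulated (0.09), erythroid (-0.08), myeloid (0.14), NF-κB (-0.03) and chaperone genes (-0.05) were not called. Without the wild type IFNα library camera no longer called interferon-stimulated (0.09), STAT target (0.25), myeloid (0.44), chaperone (-0.41), NF-κB (0.06) or oxidative phosphorylation genes (-0.09). Calls also ended without wild type vehicle for myeloid (0.74) and mast cell genes (-1.89), without Dnmt3a-/- vehicle for interferon-stimulated (0.23), STAT target (0.53) and NF-κB genes (0.30), without Dnmt3a-/- IFNα for myeloid genes (0.47), without JAK2-V617F vehicle for STAT targets (0.47), without JAK2-V617F IFNα for NF-κB genes (0.22), and without double mutant IFNα for interferon-stimulated (0.13) and NF-κB genes (0.25).

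Loss of Dnmt3a changed few single genes over the 4 pairs of libraries, and these changed strongly. Lrmda, a leucine-rich melanocyte gene (chromosome 14, 22019712 to 23056085), went from 2.37 CPM in wild type to 21 in Dnmt3a-/- and from 3.11 in JAK2-V617F to 21.3 in the double mutant given vehicle (2.95 ± 0.12, adjusted p = 0.00346). Ifi211, a PYHIN gene of the interferon-inducible cluster (chromosome 1, 173896345 to 173913046), rose from 0.109 to 5.89 CPM in the JAK2-V617F background (4.78 ± 0.27, adjusted p = 0.00839), though it could share reads with close copies, and the tRNA deaminase subunit Adat2 (1.18 ± 0.09, adjusted p = 0.0273) also rose. The long noncoding AC102496.1 (-3.05 ± 0.21, adjusted p = 0.0214) fell. A rise of mt-Nd3 (5.28 ± 0.24, adjusted p = 0.00371) went with a loss of counts at Gm28438, an unprocessed pseudogene of 345 bp on chromosome 1 close to the 348 bp of mt-Nd3. Gm28438 had 56.5 CPM in JAK2-V617F and 0 in the double mutant given vehicle, and the sum of both moved both ways: from 23 to 21.3 CPM given vehicle and 75.2 to 25.2 under IFNα without the transgene, and from 57.5 to 36.7 and 17.8 to 33.8 with it (-0.39 ± 0.03 over replicate sums). In none of the 4 pairs did it rise as mt-Nd3 alone did (0.646 to 21.3 and 1.06 to 36.7 CPM given vehicle), so the mt-Nd3 value cannot be read as expression. edgeR called 5 of 10864 genes, DESeq2 75, and edgeR 4870 over replicate sums. The edgeR count changed in most fits that left out 1 library, as given below. Without Dnmt3a-/- vehicle only mt-Nd3 was left, with 2.88 for Lrmda, 4.69 for Ifi211, 1.22 for Adat2 and -2.96 for AC102496.1; the last 3 also lost their calls without Dnmt3a-/- IFNα (4.97, 1.13 and -3.16), Ifi211 and Adat2 without wild type IFNα (4.80 and 1.21) or double mutant IFNα (4.85 and 1.20), and Adat2 without the vehicle library of wild type (1.15), of the double mutant (1.15) or JAK2-V617F IFNα (1.13). Slamf1, which encodes the sort marker CD150, was 1.10 ± 0.09 over replicate sums (adjusted p = 1.3e-08) and missed the threshold over libraries (adjusted p = 0.0738).

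Interferon-stimulated genes were higher as a list without Dnmt3a (median 0.28), with no single gene called. Within JAK2-V617F, over replicate sums without clusters 11 and 17, the list had 0.07 given vehicle and 0.40 under IFNα. The value of 0.28 and the medians that follow average vehicle and IFNα libraries, so they show no difference in untreated cells alone. MHC class I (0.12), interferon receptor and feedback (0.11), STAT target (0.09), HSC identity (0.18), HSC ageing (0.24), immediate early (0.47) and NF-κB target genes (0.23) were higher, and erythroid (-0.30), G2 and M (-0.15), chaperone (-0.31) and oxidative phosphorylation genes (-0.15) lower. By camera the adjusted p was 2.0e-12 for interferon-stimulated genes, 1.1e-05 for immediate early, 5.6e-05 for G2 and M, 9.2e-05 for oxidative phosphorylation, 0.00497 for MHC class I, HSC identity, erythroid and chaperone genes, 0.00674 for ageing, 0.016 for receptor and STAT genes, and 0.0431 for NF-κB targets. With an estimated correlation it was 0.643 to 0.728. Adjusted over the list alone, 5 immediate early genes passed. Interferon-stimulated, immediate early and G2 and M genes were called in all 8 fits that left out 1 library. HSC identity lost its call without wild type IFNα (-0.04), Dnmt3a-/- vehicle (0.08), JAK2-V617F vehicle (0.01) or double mutant IFNα (0.05), and in the largest cluster alone turned to -0.12. Camera also ended its calls in that cluster for G2 and M (-0.07), MHC class I (0.06), receptor (0.20), STAT target (0.14), erythroid (-0.06), chaperone (-0.10) and oxidative phosphorylation genes (-0.05). Without clusters 11 and 17 they ended for HSC identity (0.12), STAT target (0.10), erythroid (-0.08), chaperone (-0.18), NF-κB (0.16) and oxidative phosphorylation genes (-0.08), and without replicates 3 of the double mutant for STAT target (0.12) and NF-κB genes (0.22). NF-κB genes lost it without wild type IFNα (0.02), Dnmt3a-/- IFNα (0.32), JAK2-V617F vehicle (0.15) or double mutant IFNα (0.11). Without wild type IFNα or JAK2-V617F vehicle the calls of ageing (0.12 and 0.10), chaperone (-0.19 and -0.12) and oxidative phosphorylation genes (-0.10 and -0.08) ended. MHC class I lost its call without JAK2-V617F IFNα (0.10) or double mutant IFNα (0.06), STAT targets without wild type IFNα (0.07) or double mutant IFNα (0.11), and receptor (0.09) and erythroid genes (-0.18) without wild type vehicle.

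In the JAK2-V617F background alone, edgeR called 3 genes over library sums for Dnmt3a loss: Lrmda (2.89 ± 0.16, adjusted p = 0.0166), mt-Nd3 (5.46 ± 0.32, adjusted p = 0.0166), with the counting problem above, and Ifi211 (5.21 ± 0.35, adjusted p = 0.0231). DESeq2 called 25, and edgeR 4056 over replicate sums. Leaving out any 1 of the 4 Dnmt3a-/- or double mutant libraries left 0 calls by edgeR. Lists called higher were interferon-stimulated (0.23), MHC class I (0.19), erythroid (0.46), S phase (0.10), oxidative phosphorylation (0.09) and ribosomal protein genes (0.08), with camera adjusted p of 8.6e-09, 1.6e-06, 0.0209, 0.0476, 0.0476 and 5.6e-04, and 0.944 for each with an estimated correlation. No member of any of these lists passed alone or adjusted over its list. The medians average vehicle and IFNα libraries. Without JAK2-V617F IFNα the medians of S phase (-0.05) and oxidative phosphorylation (-0.06) turned, and camera no longer called ribosomal proteins (median 0.03, pointing down) or erythroid genes (0.16). Without double mutant vehicle ribosomal proteins turned to -0.03 and the calls of S phase (-0.01) and oxidative phosphorylation (0.00) ended, and without double mutant IFNα that of interferon-stimulated genes ended (-0.01). In the largest cluster alone S phase was at 0.01 with camera pointing down, not called. Without clusters 11 and 17 camera called neither erythroid (0.09), S phase (0.05) nor oxidative phosphorylation genes (0.06), nor erythroid (0.23) and oxidative phosphorylation genes (0.05) in the largest cluster, nor S phase (0.04) and oxidative phosphorylation (0.08) without replicates 3 of the double mutant, where the interferon-stimulated median was 0.18.

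Whether the 2 mutations add up was tested as their interaction. edgeR called 0 of 10864 genes over libraries, with 431 at an unadjusted p under 0.05; DESeq2 called 15 and edgeR 5197 over replicate sums. Without the wild type IFNα library edgeR called 1. The smallest p values belonged to Tnfsf13os (-1.29 ± 0.20), Lrmp (-1.90 ± 0.32), Bex4 (0.92 ± 0.18), Ciao2a (0.75 ± 0.15) and the metallothionein Mt1 (3.10 ± 0.61), each with an adjusted p of 0.739. As lists, erythroid (1.59), chaperone (0.57), oxidative phosphorylation (0.54), S phase (0.34), G2 and M (0.33), ribosomal protein (0.26) and MHC class I genes (0.14) were higher in the double mutant than the single effects add up to. Immediate early (-0.73), quiescence (-0.39), HSC identity (-0.39) and STAT target genes (-0.25) were lower. Camera adjusted p was 1.0e-08 for erythroid, 0.00602 for chaperone, 2.2e-11 for oxidative phosphorylation, 1.3e-06 for S phase, 3.0e-07 for G2 and M, 2.9e-10 for ribosomal, 0.0144 for MHC class I and STAT target, 7.7e-07 for immediate early, 0.00814 for quiescence and 0.0134 for HSC identity genes. With an estimated correlation it was 0.648 to 0.872. Adjusted over the list alone, 4 immediate early genes passed and no gene of the other lists. HSC identity turned to 0.06 without wild type IFNα, 0.02 without JAK2-V617F IFNα and 0.13 in the largest cluster, and lost its call without Dnmt3a-/- vehicle (-0.24) or double mutant vehicle (-0.18). The calls also ended for MHC class I without wild type vehicle (0.14), Dnmt3a-/- IFNα (0.17), JAK2-V617F IFNα (0.15) or double mutant IFNα (0.09), for STAT targets without wild type IFNα (-0.16), Dnmt3a-/- IFNα (-0.31) or JAK2-V617F vehicle (-0.29), and for chaperones without wild type IFNα (0.25) or JAK2-V617F IFNα (0.22). In the largest cluster S phase turned to -0.08, and neither it nor G2 and M (0.00), quiescence (-0.02), STAT target (-0.04) or chaperone genes (0.03) were called there; erythroid (0.15) and oxidative phosphorylation genes (0.18) were. Without clusters 11 and 17 the erythroid median was 0.32 and that of oxidative phosphorylation 0.27, both called, and camera called neither chaperone (0.22), quiescence (-0.10), HSC identity (-0.14) nor STAT target genes (-0.09).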

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

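Of the tests in this part, the leaving out of clusters 11 and 17, the fits over replicates within 1 genotype or treatment, the summed counts of mt-Nd3 and its nuclear copy, and the leaving out of replicates 3 of the double mutant were chosen after the results had been seen; the others were planned. The response to IFNα differed between libraries with and without the transgene, by the test of that difference, in 1309 genes, the first of them Ybx3 (-1.905), Ppp2cb (-2.679), Atp13a3 (-1.533), Lsp1 (1.371) and Cdk2ap1 (-1.298). Between libraries with and without Dnmt3a it differed in 2 genes, Xist (-11.01) and Tsix (-4.49). Xist was carried only by the vehicle replicates named above. Without replicates 3 of the double mutant neither gene was called (-5.39 and -2.70).

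HSC identity genes were lower (median -0.93) and megakaryocyte genes higher (1.63) under IFNα. At equal cells and UMIs the HSC identity median was -0.881. This decides little about depth, since drawing cells at random and thinning summed counts leaves the expected CPM unchanged. Without the cells of clusters 11 and 17 the HSC identity median was -0.411, less than 50% of its size with them. These erythroid-led cells could thus account for most of the fall. Still, 14 genes were lower and camera called the list with the preset correlation (adjusted p = 0.00733). Over all cells that call did not hold with an estimated correlation, which decides little. The megakaryocyte median was 1.76, which these erythroid-led cells cannot explain. Clusters led by megakaryocyte genes, such as cluster 1 with Pf4, were kept in that fit, so it does not test them. In the largest cluster alone the medians were -0.24 and 0.11, which decides nothing, since clusters were drawn by expression, with Procr among the leading genes of this one. What stays open is whether stem cells changed state within a day or other progenitors entered the sort gate.

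HSC identity genes fell less under IFNα in the JAK2-V617F libraries (median difference 1.06). At equal cells and UMIs the median difference was 1.08, which decides little about depth, for the reason given above. Without the cells of clusters 11 and 17 the median was 0.335, with 4 genes called higher and the list still called (camera adjusted p = 8.1e-06), and in the largest cluster alone, drawn in part by such genes, -0.07, not called. The larger part of this difference may therefore come from how many such cells each library held rather than from a change within comparable cells. A direct effect of the transgene on stem cells stays open for the rest.

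Few genes differed strongly with Dnmt3a loss over libraries, and some of these could mark the strain of the mice rather than the gene. A segment around Dnmt3a that came with the allele could not be judged: 0 of the 69 genes called over replicate sums with an absolute log2 change above 1 lay within 20 Mb, where 0.293 were expected from 46 tested genes. A difference between C57BL/6 substrains at Nnt is argued against, with a log2 change of 0.215 ± 0.0889. Counts of mt-Nd3 rose by 5.28 where those of the nuclear copy Gm28438 ended. Their sum moved both ways between pairs of libraries (-0.394 over all), in none of them as mt-Nd3 alone did, so a sequence difference of the mitochondrial genome or of the copy may explain that gene, and it was not tested on sequence. Ifi211 lies in a cluster of close copies that could share its reads, and a direct effect of Dnmt3a loss on it and on Lrmda stays open. Slamf1 and Ifi204, also higher without Dnmt3a, lie near it on chromosome 1 (starts at 171767127, 173747293 and, for Ifi211, 173896345). Cd48, next to Slamf1, moved both ways given vehicle, from 12.6 to 21.3 CPM without the transgene and 20.5 to 17.2 with it. A strain segment at this place was not tested.

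Splits of the 8 libraries into 4 and 4 were fitted without the genotype term. For IFNα, 1 of 35 splits, the real one, gave as many as 1987 genes, with 4 in the highest other, so chance is excluded. For JAK2-V617F 3 of 35 gave at least the real 3 genes, and for Dnmt3a loss 2 of 35 at least the real 4. These are the splits by IFNα (1987), Dnmt3a loss (4) and JAK2-V617F (3), and the others gave 0. Such shares do not decide on chance. Over replicates the 10 splits of 3 against 3 are too few for a share under 5%. There the real split, 1 of 10, called 7563 genes for IFNα in wild type, 6763 in JAK2-V617F and 3589 in the double mutant, 1546 for Dnmt3a loss in JAK2-V617F given vehicle and 2605 under IFNα, with 0 in the highest other split of each.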

How the results depend on the processing

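Of the settings in this part, those without the Dnmt3a-/- pair of libraries, without clusters 11 and 17 and without replicates 3 of the double mutant, and the fits over replicates within 1 genotype or treatment, were chosen after the data were seen. The cause of the changes below was not tested, except that fewer genes or samples were fitted where the setting says so. With the settings of the report edgeR called 3192 for IFNα, 8 for JAK2-V617F, 5 for Dnmt3a loss, 3 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 1309 for IFNα by JAK2-V617F and 2 for IFNα by Dnmt3a loss. Counts of called genes and shares over library sums were compared in 179 alternatives: 79 stayed within 1.5 times the value, 96 moved further, 3 grew in the same direction and 1 turned; over replicate sums 163 of 168 stayed. Single genes kept direction and side of the threshold in 1073 of 1425 alternatives over library sums, lost the call in 259, gained it in 88 and turned in 5; over replicate sums 554 of 556 stayed. Lists stayed in 854 of 1160, lost the call in 259, gained it in 18 and turned in 29, and over replicate sums stayed in 83 of 112. Depth limits the wild type and Dnmt3a-/- libraries most, with 830 cells in the smallest.

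DESeq2 called 4350 for IFNα, 1145 for JAK2-V617F, 75 for Dnmt3a loss, 25 for Dnmt3a loss within JAK2-V617F, 15 for the interaction of both mutations, 778 for IFNα by JAK2-V617F and 14 for IFNα by Dnmt3a loss. Without the low count filter edgeR called 5549 for IFNα, 999 for JAK2-V617F, 72 for Dnmt3a loss, 20 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 2618 for IFNα by JAK2-V617F and 171 for IFNα by Dnmt3a loss. With the filter at 20 CPM it called 1821 for IFNα, 5 for JAK2-V617F, 4 for Dnmt3a loss, 1 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 953 for IFNα by JAK2-V617F and 6 for IFNα by Dnmt3a loss. At equal depth it called 2612 for IFNα, 23 for JAK2-V617F, 12 for Dnmt3a loss, 6 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 827 for IFNα by JAK2-V617F and 22 for IFNα by Dnmt3a loss. Without cycling cells it called 1859 for IFNα, 147 for JAK2-V617F, 28 for Dnmt3a loss, 8 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 107 for IFNα by JAK2-V617F and 20 for IFNα by Dnmt3a loss. It called in the largest cluster alone 1187 for IFNα, 305 for JAK2-V617F, 200 for Dnmt3a loss, 134 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 28 for IFNα by JAK2-V617F and 48 for IFNα by Dnmt3a loss. Without clusters 11 and 17 it called 3506 for IFNα, 321 for JAK2-V617F, 45 for Dnmt3a loss, 12 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 122 for IFNα by JAK2-V617F and 46 for IFNα by Dnmt3a loss. Without replicates 3 of the double mutant it called 4159 for IFNα, 12 for JAK2-V617F, 4 for Dnmt3a loss, 3 for Dnmt3a loss within JAK2-V617F, 0 for the interaction of both mutations, 100 for IFNα by JAK2-V617F and 18 for IFNα by Dnmt3a loss, and over replicate sums 3176 against 1946 for Dnmt3a loss in JAK2-V617F given vehicle. For IFNα it called 1987 without the genotype term and 108 without the Dnmt3a-/- pair.

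Over replicate sums edgeR called 8704 for IFNα, 7104 for JAK2-V617F, 4870 for Dnmt3a loss, 4056 for Dnmt3a loss within JAK2-V617F, 5197 for the interaction of both mutations, 6723 for IFNα by JAK2-V617F and 903 for IFNα by Dnmt3a loss. With the replicate number as a block it called 8663 for IFNα, 6915 for JAK2-V617F, 4657 for Dnmt3a loss, 3865 for Dnmt3a loss within JAK2-V617F, 4959 for the interaction of both mutations, 6600 for IFNα by JAK2-V617F and 819 for IFNα by Dnmt3a loss. The numbers did not pair the samples: deviations of samples with the same number had a mean correlation of -0.0275 over 71 pairs, those with different numbers 0.0149 over 140, and 2 of 22 samples correlated best with a sample of its own number. The block is therefore given as a description.

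With 1 library left out, in a fit that assumes the lone library left in a group to vary like the others, the counts ran over 90 to 3833 for IFNα (lowest without Dnmt3a-/- IFNα), 2 to 7 for JAK2-V617F (lowest without Dnmt3a-/- IFNα), 1 to 8 for Dnmt3a loss (lowest without Dnmt3a-/- vehicle, highest without JAK2-V617F vehicle), 0 to 4 for Dnmt3a loss within JAK2-V617F (lowest without any Dnmt3a-/- or double mutant library) and 0 to 1 for the interaction of both mutations (highest without wild type IFNα). The interactions with IFNα have no residual degree of freedom without a library and were not run so. Over replicate sums, with 1 of 22 replicates left out, the counts ran over 1144 to 2523 for Dnmt3a loss in JAK2-V617F given vehicle, lowest without JAK2-V617F vehicle replicate 2, and 2269 to 4025 under IFNα. For IFNα they ran over 7150 to 8015 in wild type, 6018 to 7419 in Dnmt3a-/-, 3731 to 5252 in JAK2-V617F and 4538 to 6361 in the double mutant, and 4691 against 7184 were called in Dnmt3a-/- without clusters 11 and 17. Lists are said to turn by the direction of camera. The medians of those that turned when 1 library was left out ranged over -0.0498 to 0.217 for S phase, -0.0639 to 0.29 for oxidative phosphorylation and -0.0295 to 0.182 for ribosomal proteins in Dnmt3a loss within JAK2-V617F, where camera pointed down for ribosomal proteins, not called, at a median of 0.03 without JAK2-V617F IFNα, and -0.909 to 0.0602 for HSC identity in the interaction of both mutations. Medians of lists that lost their call also changed sign, with camera's direction kept, for HSC identity in Dnmt3a loss without wild type IFNα (-0.0408) and interferon-stimulated genes in Dnmt3a loss within JAK2-V617F without double mutant IFNα (-0.00572).

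Lists called by camera with the preset correlation numbered 12 for IFNα, 10 for JAK2-V617F, 12 for Dnmt3a loss, 6 for Dnmt3a loss within JAK2-V617F, 11 for the interaction of both mutations, 12 for IFNα by JAK2-V617F, 7 for IFNα by Dnmt3a loss. With an estimated correlation 0 were called in each comparison. fry called 9 for IFNα and 0 in each other comparison. Camera called in the largest cluster alone 2 for JAK2-V617F, 5 for Dnmt3a loss, 7 for the interaction of both mutations, 7 for IFNα by JAK2-V617F, and without clusters 11 and 17 2 for JAK2-V617F, 7 for Dnmt3a loss, 3 for Dnmt3a loss within JAK2-V617F.

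Values that turned in the largest cluster alone were, for IFNα, Procr 0.0202, Flt3 0.423, Slamf1 -0.6651, Pim2 0.244, Socs2 0.0346 and the list medians of receptor and feedback 0.133, megakaryocyte 0.109 (by camera's direction), erythroid -0.115, lymphoid -0.00582 (by camera's direction), glycolysis 0.118 and ribosomal genes -0.182. For JAK2-V617F they were HSC identity -0.143 and oxidative phosphorylation 0.0942, for Dnmt3a loss HSC identity -0.118, within JAK2-V617F S phase 0.00749 (by camera's direction), and for both mutations STAT targets -0.0423 (by camera's direction), HSC identity 0.133, S phase -0.0819 and chaperones 0.0324 (by camera's direction). For IFNα by JAK2-V617F they were interferon-stimulated -0.0113, HSC identity -0.071, myeloid -0.164, lymphoid -0.0693 and chaperone genes 0.0998, and for IFNα by Dnmt3a loss erythroid genes -0.156. Without clusters 11 and 17 oxidative phosphorylation for JAK2-V617F (0.0592), megakaryocyte genes for IFNα by JAK2-V617F (-0.048) and erythroid genes for IFNα by Dnmt3a loss (-0.0963) turned. The medians of STAT targets (-0.0138) and NF-κB targets (-0.0331) for JAK2-V617F and of G2 and M genes (-0.000453) for both mutations changed sign as well in the largest cluster and lost their calls, with camera's direction kept. Changes of sign in lists that camera called neither before nor after are not listed.

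The share of cycling cells differed by JAK2-V617F by 0.877 percentage points at 2 UMIs, against -0.567, and by -9.815 without thinning, where deeper cells reach the limit more easily; for Dnmt3a loss it was -4.335 without thinning. For IFNα it was 21.3, 17 and 27.6 at 2 UMIs, at 5 UMIs and without thinning. The library median of interferon-stimulated genes in wild type was 1.65 in the largest cluster, where the IFNα library held 27 cells, against 0.81. The hashtag settings removed 0 cells and moved nothing. The alternatives for shares of cells per cluster were not run.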

Other observations

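Of the tests in this part, the tests of both hypotheses, with the sort gate genes by cluster and the leaving out of clusters 11 and 17 and of replicates 3 of the double mutant, were chosen after the results had been seen. Genes of the sort gate and of DNA methylation also changed with IFNα. Cd48, whose protein is gated out, rose (1.39 ± 0.32, edgeR adjusted p = 0.0306), Kit fell (-0.57 ± 0.13, adjusted p = 0.0297), and Ly6a, which encodes Sca-1, missed the threshold (0.90 ± 0.28, adjusted p = 0.0553), going in CPM from 117 to 97 in wild type, 132 to 228 in Dnmt3a-/-, 184 to 437 in JAK2-V617F and 168 to 519 in the double mutant. Slamf1 had 0.10 ± 0.10. Over replicate sums Ly6a rose in JAK2-V617F (1.24 ± 0.10), the double mutant (1.56 ± 0.11) and Dnmt3a-/- (0.92 ± 0.13), and in wild type had -0.12 ± 0.12, not called by edgeR. Among 11 genes of DNA methylation 1 rose, Mbd2 (1.31 ± 0.36), and 3 fell, with Tet1 (-0.94 ± 0.22) and Dnmt3a itself (-0.61 ± 0.14, adjusted p = 0.0308) among them (list median -0.17). Mouse Jak2 stood between 39.3 and 53.5 CPM in the 8 libraries. Without single libraries all of these calls ended in some fits. Cd48 lost its call when either library of wild type (1.09), Dnmt3a-/- (1.25 and 1.26) or the double mutant (1.503) was left out, and so did Tet1 (-0.71, -0.83 and -1.04) and Dnmt3a (-0.57, -0.47 and -0.62), Mbd2 without either library of wild type (1.08) or Dnmt3a-/- (1.01) or double mutant IFNα (1.65), and Kit without either library of Dnmt3a-/- (-0.62) or the double mutant (-0.60).

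Over replicate sums, transcripts of the mitochondrial genome fell under IFNα in JAK2-V617F (15 of 16, median -0.48, camera adjusted p = 4.4e-12, 0.0564 with an estimated correlation) and in the double mutant (14 of 16, -0.37, camera adjusted p = 2.8e-07, 0.142 with an estimated correlation), with 6 up and 7 down in wild type and 6 up and 5 down in Dnmt3a-/-. Immediate early genes fell in JAK2-V617F (9 of 12, median -0.67, camera adjusted p = 0.00674, 0.404 with an estimated correlation) and had a median of 0.26 in the double mutant. Ifi204, a neighbour of Ifi211 and named here after its values were seen, was higher without Dnmt3a in the JAK2-V617F background before treatment (5.01 ± 0.36) and under IFNα (2.39 ± 0.23), and in CPM went from 0.718 to 1.65 in wild type, 7.89 to 13.1 in Dnmt3a-/-, 0.297 to 4.6 in JAK2-V617F and 9.72 to 23 in the double mutant. Cxcl10 (3.95 ± 0.56) and Il1b (3.91 ± 0.49) rose with IFNα and Xist had -9.91 ± 2.73. Xist was carried by the vehicle replicates named above. It had -7.53 without Dnmt3a-/- vehicle, -7.23 without double mutant vehicle and -7.02 without replicates 3 of the double mutant, not called in these fits. Nor was it called without either wild type library (-10.50 and -10.51).

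Camera called none of the other lists for IFNα over libraries; with the members up and down by edgeR and the median these were receptor and feedback genes (2 and 2 of 12, -0.11), STAT targets (0 and 5 of 15, -0.14), HSC ageing (6 and 3 of 16, 0.24), myeloid (1 and 4 of 7, -0.67), stromal (0 and 0 of 2, -0.18), quiescence (2 and 4 of 13, -0.13), p53 targets (3 and 0 of 12, 0.25), immediate early (2 and 3 of 12, -0.45), NF-κB targets (3 and 2 of 13, 0.02), apoptosis (2 and 0 of 16, 0.04), glycolysis (2 and 4 of 15, -0.11), cholesterol synthesis (0 and 3 of 15, -0.15), ribosomal protein (4 and 2 of 83, 0.00), mitochondrial genome (0 and 3 of 16, -0.18) and sort gate genes (1 and 1 of 4, 0.50).

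A hypothesis for the fall of HSC identity genes under IFNα is that IFNα raises Sca-1 on progenitors, so that more cells other than LT-HSCs may pass the gate. The removal of the erythroid-led clusters 11 and 17 took the HSC identity median from -0.93 to -0.411, while the megakaryocyte median went to 1.76, which this part of the idea does not account for. Over all cells Ly6a runs against the idea: it had -0.12 in wild type, where HSC identity genes fell most (-1.46), and rose most in JAK2-V617F and the double mutant (1.24 and 1.56), where they fell least (-0.33 and -0.51). These values mix cells, however. In wild type Ly6a went from 134 to 231 CPM outside clusters 11 and 17, and inside them it stood at 24 CPM under IFNα against 15.3 in the 38 such cells given vehicle (log2 ratio 0.642). Cd48 is not accounted for by these clusters: outside them it went from 12.8 to 55.6 CPM in wild type, 21.3 to 53.9 in Dnmt3a-/-, 20.5 to 25.8 in JAK2-V617F and 17.1 to 33.7 in the double mutant, against 58.7, 84.3, 59.6 and 57.3 inside them under IFNα. The sort also took only CD48- CD150+ cells, so progenitors with CD48 on their surface would be left out even with more Sca-1. The other genotypes had at most 5 such cells given vehicle, and Sca-1 protein was not measured, so the idea stays open.

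A second hypothesis is that Dnmt3a loss strengthens the interferon response; the difference in response was 0.41 over all cells. The cells of clusters 11 and 17 are argued against as its source, with 0.498 without them. So are replicates 3 of the double mutant as the whole of it over both JAK2 backgrounds together, with 0.292 without them. At equal depth it was 0.37, which decides little, since thinning leaves the expected CPM unchanged. Camera called the list in each of these fits with the preset correlation. Over all cells it did not with an estimated one (adjusted p = 0.838), which decides little. The largest cluster gave 0.516, which decides nothing, because its cells are led in part by genes of the list such as Ifit3 and only 27 came from wild type under IFNα. Within the JAK2-V617F background little of the difference was left without replicates 3 of the double mutant, 0.13 given vehicle and 0.20 under IFNα, and the response median was then lower in the double mutant (1.42) than in JAK2-V617F (1.54), the other way round from all replicates (1.62 and 1.55). In that background these replicates may thus account for the larger response. Sex differed between treatments in Dnmt3a-/- mice and between replicates in the double mutant, where replicate 3 given vehicle carried Xist and replicate 3 under IFNα carried neither Xist nor Y transcripts and had more of the transgene than the others, and 1 library per group leaves the spread between libraries unknown. The hypothesis therefore stays open. Sorting with a marker that IFNα leaves unchanged, mice of 1 sex, and more than 1 library per group would be needed for both.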
